A study of Mus musculus with 9 samples.

How the data were processed

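Bulk RNA-seq of mouse intestinal epithelium was analysed from the deposited processed tables. The study held 9 libraries in 3 groups of 3: ileum and colon epithelium of Satb2 f/f mice (WT ileum and WT colon), and colon epithelium of Vil-CreER;Satb2 f/f mice (Satb2 KO colon). Per the labels' protocols, the epithelium was released with EDTA 30 days after tamoxifen, RNA was extracted with a Qiagen kit, and non-directional mRNA libraries were made with a NEBNext Ultra kit. The labels did not say whether the 3 replicates of a group came from separate animals, so the p-values may measure technical spread in place of differences between animals. Groups were taken from the labels alone.

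Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to the mouse genome build GRCm38 with STAR and counted per gene with featureCounts, and DESeq2 was used for normalization; versions were not given in the sources used here. The deposited raw table held 1 integer count per gene and library for 54735 genes, of which 30261 had at least 1 count. The deposited normalized table held, per the labels, the same signal scaled for library size for 14701 genes; each value was checked to equal the raw count divided by 1 factor per library (largest relative deviation 4.95e-10). The deposited table of RPKM values held 21698 genes; for 12611 of them the values were checked to equal the raw count over the column total and 1 length per gene (largest relative deviation 2.78e-07). All 27 library columns of the 3 tables belonged to the 9 libraries. Counting was unstranded, so reads from genes that overlap on opposite strands could not be told apart. Gene positions came from the GENCODE M21 annotation of GRCm38. Of the 168 named genes with a position, 41 shared exon bases with another gene, 38 of them with a gene on the opposite strand.

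Each library held 18.9 to 27.5 M counts. At this depth a floor of 3 counts in 1 library corresponded to 0.109 to 0.159 CPM. A fold change against a group without a single count was given as a lower bound, from 3 counts over the group; against a group with 1 to 3 counts it was given as a ratio with an exact 95% interval for counting error only. CPM were raw counts over the library size times the TMM factor, times 1e+06.

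The test used edgeR 4.0.16 in R 4.3.3: filterByExpr by group (15976 genes kept, with 99.8 to 99.9% of the counts), TMM factors (0.788 to 1.13), 1 model with a mean for each of the 3 groups over all 9 libraries, estimateDisp, and the quasi-likelihood F test with a prior count of 0.125. The comparisons were Satb2 KO colon with WT colon, WT ileum with WT colon, and Satb2 KO colon with WT ileum. The 2 wild-type tissues differ in location, and the comparison with WT ileum joins the location with the genotype. Adjusted p-values were Benjamini-Hochberg values over all tested genes of a comparison, and a gene passed at 0.05. Here ± after a mean is the standard deviation over 3 libraries; ± after a log2 fold change is an approximate standard error, the absolute log2 fold change over the square root of F.

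The sets of genes comprised 37 lists of gene functions, cell types and stress responses. They were tested with camera of limma 3.58.1 at the preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Members that passed were counted over all genes and, separately, with the adjustment made over the list alone. The shift of the knockout colon was measured as a share and as a slope. The share covered genes that passed with at least a 4-fold difference between WT ileum and WT colon. It counted those that passed in the same direction in the knockout colon, with an exact 95% binomial interval that treats genes as independent. The slope, of 1 set of log2 fold changes on the other, covered all tested genes without a threshold. The 2 comparisons share the WT colon libraries, so 100 simulated data sets without any change gave the covariance due to noise, which was taken off before the slope was computed. A second version chose the genes with 2 WT colon libraries and measured the knockout change against the third.

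Genes were named from a set given by a rule: Satb2; for each comparison, the 10 largest increases and 10 largest decreases that passed, with a mean log2 CPM of at least 3 and all 3 libraries of 1 group beyond all 3 of the other; up to 4 members that passed with the largest changes in each list; and every member of the lists of intestinal transcription factors and posterior Hox genes that passed. The text gives part of this set, mostly genes that kept their call with each library left out, a choice made after values were seen. Predicted genes were counted but not named, and members that did not pass may be named with values. Members of near-identical families (Defa, Lyz, Reg3, Ces2 and others) were marked as uncertain, since reads may not be told apart. The test, the comparisons, the lists, the naming rule and the alternatives below were set before the data were examined, unless stated as chosen later.

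Alternatives were median-of-ratios factors and library size alone in place of TMM; no filter beyond 1 count; a filter of 1 CPM in 3 libraries; and DESeq2 1.42.0 (Wald test, the same design). Others were limma on log2(RPKM + 0.1) with RPKM of at least 0.5 in 3 libraries, with a pseudocount of 1, and without that filter, the 6 libraries of a comparison alone, the replicate number as a block, thresholds of 2-fold and 8-fold for the shift, and each library left out in turn. Fits of replicates 2 and 3 alone, with replicate 1 as a covariate, and of the slope with simulated noise also taken off the variance were added after values were seen. The replicate numbers come from the labels, which name no pairing. In the deposited column names, WT ileum and WT colon share the same genotype and number. These numbers could therefore mark animals that gave both tissues, which was not stated, and the main fit did not pair them. They were checked as pairs: over the tested genes, deviations from the group means correlated above 0.1 in 9 of 9 pairs of libraries with the same number (0.261 to 0.559, against -0.484 to 0.414 for other numbers), so the fit with the block was computed for each result. Only 4 of the 9 libraries correlated best with their own number in both other groups. Replicates 2 and 3 of different groups also correlated, at 0.215 to 0.414, so the 9 of 9 pairs do not show that the numbers mark pairs. Between WT ileum and WT colon, replicates 2 and 3 correlated at 0.312 and 0.267 with the same number. With the other number they correlated at 0.390 and 0.414. The block also joined knockout libraries to the WT libraries of the same number, so it was not a test of pairs within WT alone.

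Each test was tested on simulated data drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those with a mean of at least 20 counts per library. The recovered shares below therefore do not cover genes with fewer counts. For Satb2 KO colon with WT colon (15603 genes), edgeR recovered 6% of the 2-fold and 58% of the 4-fold changes, and DESeq2 21% and 84% with 42 false calls; limma recovered 6% and 56% (15367 genes). For WT ileum with WT colon (15578 genes) edgeR recovered 2% and 51% with 4 false calls, and for Satb2 KO colon with WT ileum (15630 genes) 2% and 49% with 1 false call. The list tests found a shifted list of 20 genes in each of the 3 comparisons, with 1 false call, by fry for Satb2 KO colon with WT colon. The simulated genes were drawn independently, so this does not show how the list tests behave for genes that vary together. A simulated slope of 0.5 came back as 0.368, and as 0.492 with the noise also taken off the variance (15488 genes). No library was left out of the test, and no reads were available, so values per exon were not computed.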

Results

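The data comprised 9 RNA-seq libraries of mouse intestinal epithelium taken 30 days after tamoxifen: WT ileum, WT colon and Satb2 KO colon, with 3 libraries each. Replicates 1 to 3 held 20.8, 21.3 and 18.9 M counts in WT ileum, 23.1, 21.6 and 23.4 M counts in WT colon, and 19.9, 25.8 and 27.5 M counts in Satb2 KO colon. The first principal component (45.6% of the variance) placed WT colon at 68.9 to 78.3, Satb2 KO colon at -33.0 to -27.4 and WT ileum at -50.4 to -41.0. The second (22.5%) placed replicate 1 of every group at 41.3 to 62.6 and the other replicates below zero. Satb2, Apoa4, Slc51a, Cubn, Gata5, Gata6, Maf, Hoxa7, Hoxa11, Sult1a1, Cyp2c55, Ciita, Ptgs1, Cd3e, Axin2 and Fam234b share exon bases with a gene on the other strand, and their counts are uncertain because counting was unstranded. The values of Hoxa9 and Olfm4 also include exon bases of a second gene on the same strand.

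**Figure D1:**
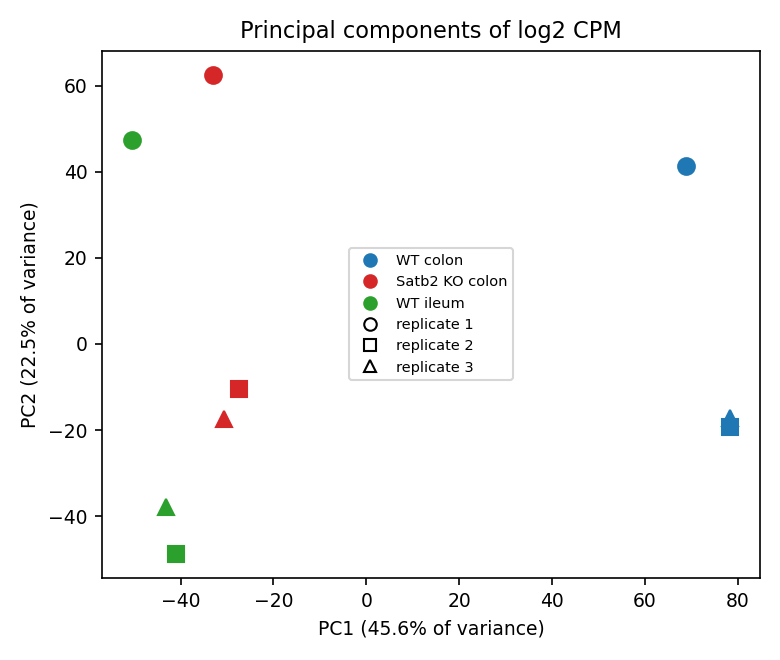
Scores of the 9 libraries on the first 2 principal components of log2 CPM, coloured by group (n = 3 each), with the marker shape giving the replicate number.

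Satb2 itself (chromosome 1, bases 56793981 to 56978650, reverse strand, GRCm38) was lower in the knockout colon and lowest in ileum. Its level in replicates 1 to 3 was 200.2, 207 and 228 CPM in WT colon, 74.5, 113 and 120.5 CPM in Satb2 KO colon, and 27.8, 36.3 and 44.6 CPM in WT ileum. The knockout colon kept 48.4% of the mean WT colon level of Satb2 (103 ± 24.6 against 212 ± 14.4 CPM, n = 3 each), a log2 fold change of -1.05 ± 0.24 (edgeR, Benjamini-Hochberg-adjusted p = 0.0247). This call for Satb2 was lost without WT colon replicate 1 (edgeR, Benjamini-Hochberg-adjusted p = 0.0549), 2 (0.0784) or 3 (0.0965), and without knockout replicate 2 (0.0735) or 3 (0.0502), with Satb2 lower in the knockout colon each time. The tables count reads over the whole Satb2 gene, so the level of the deleted part alone was not measured. WT ileum held 36.2 ± 8.36 CPM of Satb2, a log2 fold change of -2.55 ± 0.25 from WT colon (edgeR, Benjamini-Hochberg-adjusted p = 0.000201).

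The first comparison asked which transcripts changed in colon epithelium of the Satb2 knockout; Satb2 encodes a chromatin-binding regulator of transcription. Some genes for digestion and absorption, the main tasks of the small intestine, rose from traces to high levels in Satb2 KO colon. Sis, which encodes sucrase-isomaltase, went from 4.02 ± 2.66 CPM in WT colon to 3913 ± 170.2 CPM in Satb2 KO colon (n = 3 each; log2 fold change 9.92 ± 0.65; edgeR, Benjamini-Hochberg-adjusted p = 2.77e-05). The peptidase gene Anpep rose from 3.66 ± 1.34 to 3974 ± 1523 CPM (10.08 ± 0.58 on the log2 scale). Enpep rose from 3.10 ± 1.06 to 1323 ± 439 CPM (8.74 ± 0.49), and the amino acid transporter gene Slc6a19 from 0.866 ± 0.378 to 835 ± 315 CPM (9.90 ± 0.54). Apoa4, an apolipoprotein of fat absorption without a single count in WT colon, reached 897 ± 113 CPM, at least 22445-fold higher (edgeR, Benjamini-Hochberg-adjusted p = 6.83e-06).

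Over all 15976 tested genes, 901 were higher and 674 lower in Satb2 KO colon than in WT colon, and 782 and 603 of these changed at least 2-fold. The numbers moved with the setting. Without WT colon replicate 2 the test called 511 higher and 302 lower, and without WT colon replicate 3 489 and 316. Without knockout replicate 2 it called 582 and 279, and without knockout replicate 3 589 and 322. With the replicate number as a block it called 1461 higher and 1267 lower. Scaling by library size alone gave 618 higher and 1007 lower, so the higher share of the calls was 38.0% in place of 57.2%. The median log2 fold change of all genes was then -0.30 in place of -0.01. On RPKM, which is likewise scaled by the column total without TMM factors, limma called 565 higher and 992 lower (36.3%). The median log2 fold change was then -0.28, so RPKM is not a scaling separate from library size alone.

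The lists of absorptive genes rose almost as a whole in Satb2 KO colon. Of 16 tested brush border enzyme genes 15 rose, Sis and Anpep among them, and 1 did not pass (15 adjusted over the list alone). Of 19 genes of fat absorption 16 rose and 3 did not pass (17 adjusted over the list alone). Apoa1 stood at 4144 ± 2168 against 0.186 ± 0.174 CPM (log2 fold change 14.40 ± 1.02) and the cholesterol carrier gene Npc1l1 at 498 ± 229.8 against 0.815 ± 0.309 CPM (9.25 ± 0.64). Of 19 nutrient and vitamin transporter genes 17 rose and 2 did not pass (18 adjusted over the list alone); Cubn went from 2.88 ± 1.49 to 241 ± 67.7 CPM (6.39 ± 0.55). By camera with Benjamini-Hochberg adjustment over the lists, the adjusted p-values of these 3 lists with an estimated correlation were 0.000519, 0.000178 and 0.00255. Of 7 bile acid genes 5 rose and 2 did not pass (5 adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 5.55e-07, and adjusted p = 0.0639 with an estimated correlation). The ileal bile acid transporter gene Slc10a2 rose from 94.9 ± 19.7 to 1109 ± 82.1 CPM (3.55 ± 0.47; edgeR, Benjamini-Hochberg-adjusted p = 0.00146) and Slc51a from 61.3 ± 34.6 to 585 ± 60.3 CPM (3.25 ± 0.43).

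**Figure D2:**
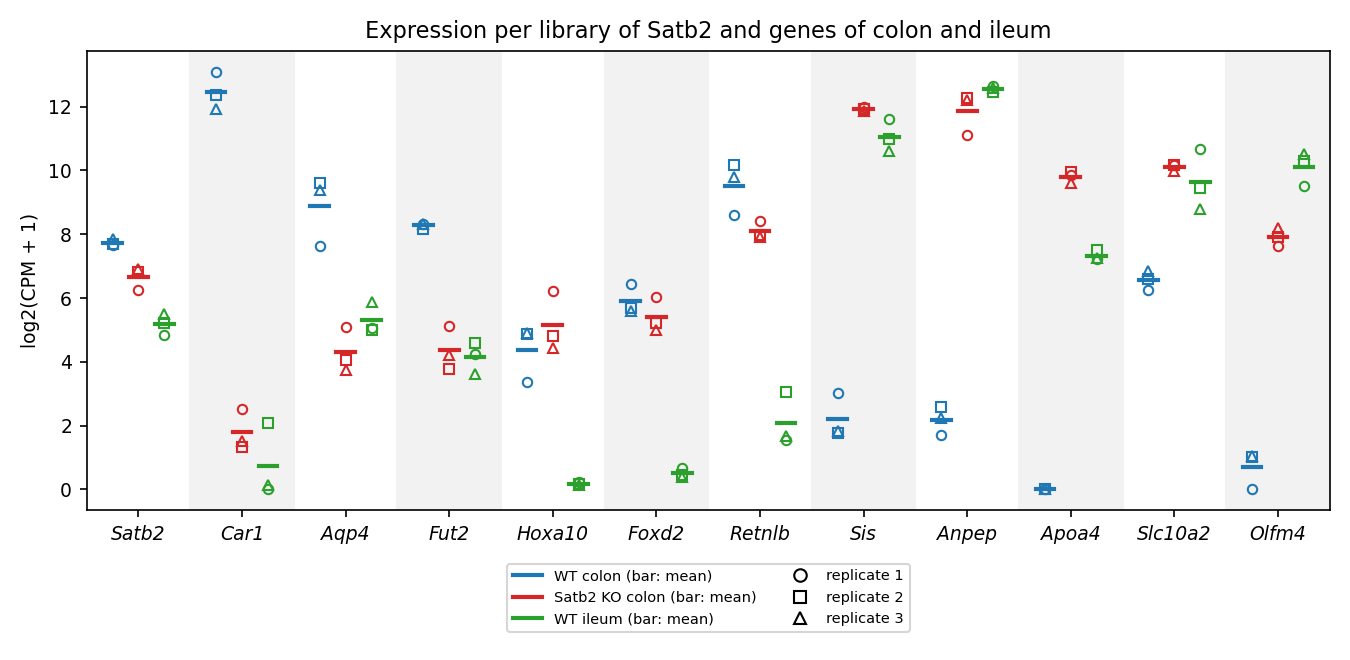
Level of 12 genes in each of the 9 libraries as log2(CPM + 1), coloured by group; bars are the means of 3 libraries.

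Some genes of water and ion handling in the colon fell. Car1, a carbonic anhydrase gene, dropped from 5958 ± 2502 CPM in WT colon to 2.70 ± 1.76 CPM in Satb2 KO colon (log2 fold change -11.13 ± 1.55; edgeR, Benjamini-Hochberg-adjusted p = 0.00192). The water channel gene Aqp4 dropped from 549 ± 310.1 to 20.5 ± 11.3 CPM (-4.74 ± 0.62). Aqp8 had 3 counts left in the knockout colon against 363 ± 287 CPM in WT colon, a ratio of 7932 with a counting interval of 2714 to 38466. Of 20 tested genes of this list 9 fell, 2 rose and 9 did not pass (11 fell and 2 rose adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 0.000202, and adjusted p = 0.194 with an estimated correlation). In these genes 5 fell without WT colon replicate 2, WT colon replicate 3 or knockout replicate 3, and 4 without knockout replicate 2; 1 in place of 2 rose in every fit without a library except that without WT ileum replicate 1.

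Genes of some enzymes that build mucin sugar chains changed too. Fut2, which adds fucose, fell from 311 ± 19.4 to 21.4 ± 11 CPM (log2 fold change -3.86 ± 0.41; edgeR, Benjamini-Hochberg-adjusted p = 0.000387). St6galnac6 fell from 584 ± 113 to 61.2 ± 26.1 CPM (-3.26 ± 0.41), and B3gnt6 from 51.6 ± 10.3 to 4.20 ± 1.33 CPM (-3.61 ± 0.37). Of these 19 tested genes 5 fell, 2 rose and 12 did not pass (6 fell and 2 rose adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 0.00069, and adjusted p = 0.0784 with an estimated correlation). Fitted with the replicate block 8 of them fell; neither of the rising ones passed without WT colon replicate 2, and 1 of them passed without WT colon replicate 3 or any knockout replicate. Among the largest decreases of all genes were the peroxidase gene Lpo (485 ± 272 to 0.180 ± 0.170 CPM, -11.20 ± 0.91) and the sulfotransferase gene Sult1a1 (354 ± 118 to 0.276 ± 0.129 CPM, -10.22 ± 0.43; edgeR, Benjamini-Hochberg-adjusted p = 6.83e-06). Of 24 xenobiotic metabolism genes 11 rose, 1 fell and 12 did not pass (13 rose and 4 fell adjusted over the list alone); 7 rose without WT colon replicate 2 or knockout replicate 3, 2 fell without WT colon replicate 1 or knockout replicate 1, and 3 fell with the replicate block. Abcc2 rose from 0.804 ± 0.102 to 295 ± 109 CPM (8.51 ± 0.39) and Cyp4f14 from 43.3 ± 25.9 to 758 ± 132 CPM (4.13 ± 0.42), while Cyp2c55 fell from 2416 ± 830.4 to 151 ± 47.7 CPM (-4.0 ± 0.67). The xenobiotic list kept its call with an estimated correlation (camera with Benjamini-Hochberg adjustment, p = 0.0341).

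Paneth cells, which secrete antimicrobial peptides at the base of small intestinal crypts, are rare or absent in mouse colon. Of 17 tested Paneth cell genes 12 rose in Satb2 KO colon and 5 did not pass (12 rose and 1 fell adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 3.2e-39, and 0.00602 with an estimated correlation). Many genes of this list belong to the near-identical Defa family, so the 12 are not independent markers. The summed level of the list did not rise throughout. In replicates 1 to 3 it was 33.4, 7619 and 4872 CPM in WT colon, and 1472, 2575 and 4555 CPM in Satb2 KO colon. Defa30, from a near-identical family and therefore uncertain as a single gene, stood at 141 ± 25.4 CPM with no count in WT colon, at least 3634-fold higher (edgeR, Benjamini-Hochberg-adjusted p = 7.15e-05). The crypt gene Olfm4 rose from 0.700 ± 0.606 to 244 ± 47.6 CPM (log2 fold change 8.44 ± 0.95; edgeR, Benjamini-Hochberg-adjusted p = 0.000572). The hormone gene Cck rose from 1.30 ± 0.467 to 23.5 ± 5.90 CPM (4.16 ± 0.42), and Gip from no count to 3.91 ± 2.33 CPM, at least 88.5-fold higher. Of 18 tested enteroendocrine genes 6 rose, 1 fell and 11 did not pass (7 rose and 2 fell adjusted over the list alone); 3 rose without WT colon replicate 3, and 2 fell with the replicate block. The list was called upward (camera with Benjamini-Hochberg adjustment, p = 0.0231), but not with an estimated correlation (0.381) or the replicate block (0.135). The tuft cell genes Ptgs1 (2.37 ± 0.624 to 25.5 ± 7.88 CPM, 3.42 ± 0.47) and Hck (9.35 ± 1.32 to 87.6 ± 68.8 CPM, 3.23 ± 0.56) rose. Of 11 tested tuft cell genes 9 rose and 2 did not pass (11 adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 2.94e-08, and adjusted p = 0.255 with an estimated correlation). Only 3 of them rose without WT colon replicate 1 or 2, and 4 without WT colon replicate 3 or knockout replicate 1.

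A part of the intestinal transcription factors rose and others fell in Satb2 KO colon. Maf went from 10.1 ± 1.60 to 174 ± 49.4 CPM (log2 fold change 4.10 ± 0.32; edgeR, Benjamini-Hochberg-adjusted p = 6.32e-05). Gata5 rose from 0.995 ± 0.368 to 28.5 ± 14.5 CPM (4.83 ± 0.43), Hnf4g from 41.1 ± 5.78 to 113 ± 18.5 CPM (1.45 ± 0.22) and Gata6 from 45.9 ± 10.1 to 114 ± 11.9 CPM (1.32 ± 0.22). Pparg fell from 109 ± 18.8 to 28.4 ± 7.82 CPM (-1.95 ± 0.29), Foxa1 from 110.1 ± 9.89 to 45.8 ± 2.69 CPM (-1.27 ± 0.22) and Hnf1b from 36.1 ± 0.958 to 16.8 ± 0.589 CPM (-1.10 ± 0.18). Of 34 tested factors 11 rose, 4 fell and 19 did not pass (14 rose and 5 fell adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 0.0151, and adjusted p = 0.399 with an estimated correlation). The 4 that fell were Pparg, Foxa1, Hnf1b and Satb2 itself. Satb2 is the gene targeted in the knockout, so its fall is not a separate result. Of the 34 factors 5 rose without WT colon replicate 2 or 3, and 7 without knockout replicate 2 or 3. Of 11 tested posterior Hox genes 1 fell and 10 did not pass (1 fell adjusted over the list alone). With replicates 2 and 3 alone, a fit chosen after values were seen, 5 of them fell and 1 rose. Over all libraries the 1 that fell was Hoxd8 (5.58 ± 2.11 to 0.621 ± 0.230 CPM, -3.14 ± 0.49); Hoxa10 stood at 40.4 ± 28.9 CPM in Satb2 KO colon and 22.2 ± 11.1 CPM in WT colon, and Hoxa9 at 22.7 ± 6.01 and 32.0 ± 22.2 CPM.

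Some genes of the interferon response, a defence against viruses and microbes, fell in Satb2 KO colon. The list was also lower in WT ileum than in WT colon, as given below. Ifit2 dropped from 78.2 ± 7.37 to 7.30 ± 1.13 CPM (log2 fold change -3.42 ± 0.42; edgeR, Benjamini-Hochberg-adjusted p = 0.000893) and Gbp3 from 22.7 ± 11.7 to 1.84 ± 0.498 CPM (-3.63 ± 0.50). Of 21 tested genes 5 fell and 16 did not pass (9 adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 7.12e-07, and adjusted p = 0.151 with an estimated correlation). Fitted with the replicate block 11 of them fell; 3 fell without WT colon replicate 2, and 2 without WT colon replicate 3, knockout replicate 2 or knockout replicate 3. Ciita, the activator of MHC class II genes, fell from 84.0 ± 51.8 to 15.6 ± 6.37 CPM (-2.43 ± 0.47; edgeR, Benjamini-Hochberg-adjusted p = 0.0111). It was the 1 of 7 tested MHC class II genes that fell, and 6 did not pass (5 adjusted over the list alone, 6 with the replicate block); 2 fell without WT ileum replicate 1 and 4 without knockout replicate 1. Of 8 genes of B and plasma cells 1 fell and 7 did not pass (1 adjusted over the list alone, 2 with the replicate block); it no longer passed without WT colon replicate 1 or knockout replicate 1 or 3. No T cell gene of 12 passed, but 3 did without WT ileum replicate 1 and 1 did without WT ileum replicate 3 or with the block. Camera with Benjamini-Hochberg adjustment called these 3 lists downward (p = 0.00190, 0.0323 and 0.0296), but none with an estimated correlation (0.504, 0.621 and 0.688). Camera with Benjamini-Hochberg adjustment lost the B and plasma cell list without knockout replicate 3 (adjusted p = 0.0959) and the T cell list without WT colon replicate 1 (0.154).

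The second comparison set the normal small intestine beside the normal colon, the frame for the change in the knockout. WT ileum carried most of the digestive, absorptive and Paneth cell transcripts, and WT colon many of those of ion and water transport and of posterior Hox genes. Lyz1, an antimicrobial gene of Paneth cells (uncertain, from a near-identical family), stood at 7613 ± 2457 CPM in ileum and 0.185 ± 0.115 CPM in colon (n = 3 each; log2 fold change 15.29 ± 0.95; edgeR, Benjamini-Hochberg-adjusted p = 1.57e-05). Anpep stood at 6021 ± 425 against 3.66 ± 1.34 CPM (10.68 ± 0.59), Sis at 2222 ± 786 against 4.02 ± 2.66 CPM (9.11 ± 0.63), and the bile acid binding gene Fabp6 at 3739 ± 1668 against 10.5 ± 17.0 CPM (8.47 ± 1.59). Car1 stood at 1.10 ± 1.81 CPM in ileum against 5958 ± 2502 CPM in colon (-12.35 ± 1.62), and Car2 at 1.42 ± 0.972 against 534 ± 139 CPM (-8.57 ± 1.33).

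Between WT ileum and WT colon, 881 genes were higher in ileum and 859 lower. Without WT colon replicate 2 the test called 560 higher and 508 lower, and without WT colon replicate 3 546 and 506; 557 were lower without WT ileum replicate 2 and 560 without WT ileum replicate 3. With the replicate number as a block it called 1340 higher and 1399 lower. Among limma calls on RPKM 628 were higher and 961 lower, a higher share of 39.5% in place of 50.6%. Scaling by library size alone gave 711 higher and 976 lower (42.1%) and moved the median log2 fold change of all genes from 0.08 to -0.08.

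All 16 brush border enzyme genes were higher in ileum than in colon (16 adjusted over the list alone). So were 18 of 19 transporter genes, with 1 that did not pass (18 adjusted over the list alone). Of 17 Paneth cell genes 12 were higher and 5 did not pass (12 higher and 1 lower adjusted over the list alone), and 1 was lower with the replicate block. Of 19 genes of fat absorption 15 were higher, 1 was lower and 3 did not pass (16 and 1 adjusted over the list alone). Of 20 genes of colonic ion and water transport 11 were lower and 9 did not pass (15 adjusted over the list alone). Of 19 mucin glycosylation genes 8 were lower, 10 did not pass and 1 was higher (11 lower and 2 higher adjusted over the list alone). The higher gene no longer passed without WT colon replicate 1 or 2, and 2 were higher with the replicate block. Hydration and mucus genes with large differences were Aqp8, with no count in ileum and 363 ± 287 CPM in colon (at least 7201-fold), and St6galnac6 at 5.04 ± 2.26 against 584 ± 113 CPM (log2 fold change -6.85 ± 0.49). Camera with Benjamini-Hochberg adjustment kept the calls of the brush border (p = 0.000371), transporter (0.00166), Paneth (0.00275), fat absorption (0.000371), ion and water (0.0156) and mucin (0.00657) lists with an estimated correlation.

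Positional genes separated the tissues sharply. Hoxa10 (chromosome 6, bases 52231197 to 52240854, reverse strand, GRCm38) stood at 0.132 ± 0.0316 CPM in ileum against 22.2 ± 11.1 CPM in colon (log2 fold change -7.34 ± 0.78; edgeR, Benjamini-Hochberg-adjusted p = 0.000291). Hoxa9 stood at 0.107 ± 0.0926 against 32.0 ± 22.2 CPM (-8.24 ± 0.99), and Hoxa7 at 0.155 ± 0.149 against 46.0 ± 24.0 CPM (-8.11 ± 0.80). Of 11 tested posterior Hox genes 7 were lower in ileum and 4 did not pass (10 adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 1.49e-12, and 0.00235 with an estimated correlation). The forkhead gene Foxd2 stood at 0.433 ± 0.155 against 61.0 ± 21.6 CPM (-7.13 ± 0.47). In the other direction Gata5 stood at 107 ± 15.9 CPM in ileum against 0.995 ± 0.368 CPM in colon (6.74 ± 0.46). Maf stood at 354 ± 91.3 against 10.1 ± 1.60 CPM (5.12 ± 0.33), and Hnf4g at 248 ± 42.9 against 41.1 ± 5.78 CPM (2.59 ± 0.22).

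Single genes of secretion, crypts and defence also differed by location, while 10 of 14 tested goblet cell genes and 11 of 13 antimicrobial genes did not pass. Of the goblet cell genes 3 were lower in ileum and 1 was higher, and 4 were lower with the replicate block. With replicates 2 and 3 alone, a fit chosen after values were seen, 10 were lower and 2 higher. Camera with Benjamini-Hochberg adjustment called the goblet cell list downward (p = 0.0340), but not with an estimated correlation (0.909). With the replicate block 4 antimicrobial genes in place of 1 were higher and 2 in place of 1 lower, and 3 were lower without WT ileum replicate 1. The colonic goblet cell gene Retnlb stood at 3.81 ± 3.01 CPM in ileum against 807 ± 386 CPM in colon (log2 fold change -7.71 ± 0.70; edgeR, Benjamini-Hochberg-adjusted p = 0.000123), and Klk1 at 110.0 ± 24.0 against 745 ± 8.53 CPM (-2.76 ± 0.40). Reg3a is an antimicrobial lectin gene of a near-identical family and so uncertain. It stood at 128 ± 22.7 CPM in ileum against 0.833 ± 0.0791 CPM in colon (7.26 ± 0.37). Olfm4 stood at 1143 ± 374 against 0.700 ± 0.606 CPM (10.67 ± 1.03), Axin2 at 105 ± 25.8 against 47.0 ± 2.81 CPM (1.16 ± 0.22), and the hormone gene Nts at 73.2 ± 25.1 against 7.94 ± 0.505 CPM (3.20 ± 0.47). Ifit2 was lower in ileum, at 4.18 ± 2.54 against 78.2 ± 7.37 CPM (-4.23 ± 0.43). Of 21 tested interferon response genes 7 were lower in ileum and 14 did not pass (13 lower adjusted over the list alone, 12 with the replicate block). Camera with Benjamini-Hochberg adjustment called this list downward (p = 3.17e-08), but not with an estimated correlation (0.0684). The ketogenesis gene Hmgcs2 stood at 28.3 ± 38.6 CPM in ileum against 1636 ± 624 CPM in colon (-5.85 ± 1.02; edgeR, Benjamini-Hochberg-adjusted p = 0.00500).

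The change in the knockout colon ran along this difference between the tissues. Of 514 genes at least 4-fold higher in ileum than in colon, 372 (72.4%, 95% interval 68.3 to 76.2%) were also higher in Satb2 KO colon, Sis, Anpep and Apoa4 among them. Of 441 genes at least 4-fold lower in ileum, 268 (60.8%, 95% interval 56.0 to 65.4%) were lower in Satb2 KO colon, Car1, Aqp8 and Fut2 among them, and 1 was higher. In total 606 genes were higher and 437 lower in both comparisons with WT colon. A further 3 genes were higher in the knockout and lower in ileum, and 2 the reverse. Independent lists as long as those of the comparisons would share 49.7 higher and 36.2 lower genes. These values leave out the noise of the WT colon libraries that both comparisons share. The intervals treat genes as independent and leave out the spread between libraries.

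The median log2 fold change of the ileum-enriched genes was 3.25 in Satb2 KO colon and 3.96 in ileum, and that of the colon-enriched genes -2.15 and -3.45. The log2 fold changes of the knockout and of ileum, both from WT colon, correlated at 0.73 over the tested genes; simulated libraries without change correlated at 0.49 through the shared WT colon libraries. The slope of the knockout change on the ileum difference, over all tested genes, was 0.637 once the simulated covariance (0.193 of 1.77) was removed. It was 0.399 without the filter of low counts, and in simulated data a true slope of 0.5 came back as 0.368. The simulation left out the deviations that libraries with the same replicate number share (correlations of 0.261 to 0.559). For genes chosen with a pair of WT colon libraries and measured against the third, 94.8 to 98.5% of the ileum-enriched genes had a positive and 81.1 to 95.2% of the colon-enriched genes a negative knockout change. Compared with ileum itself, 73 of the 514 ileum-enriched genes (14.2%) were lower in Satb2 KO colon and 91 of the 441 colon-enriched genes (20.6%) were higher. In the opposite direction 11 ileum-enriched genes were higher than in ileum and 4 colon-enriched genes lower.

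**Figure D3:**
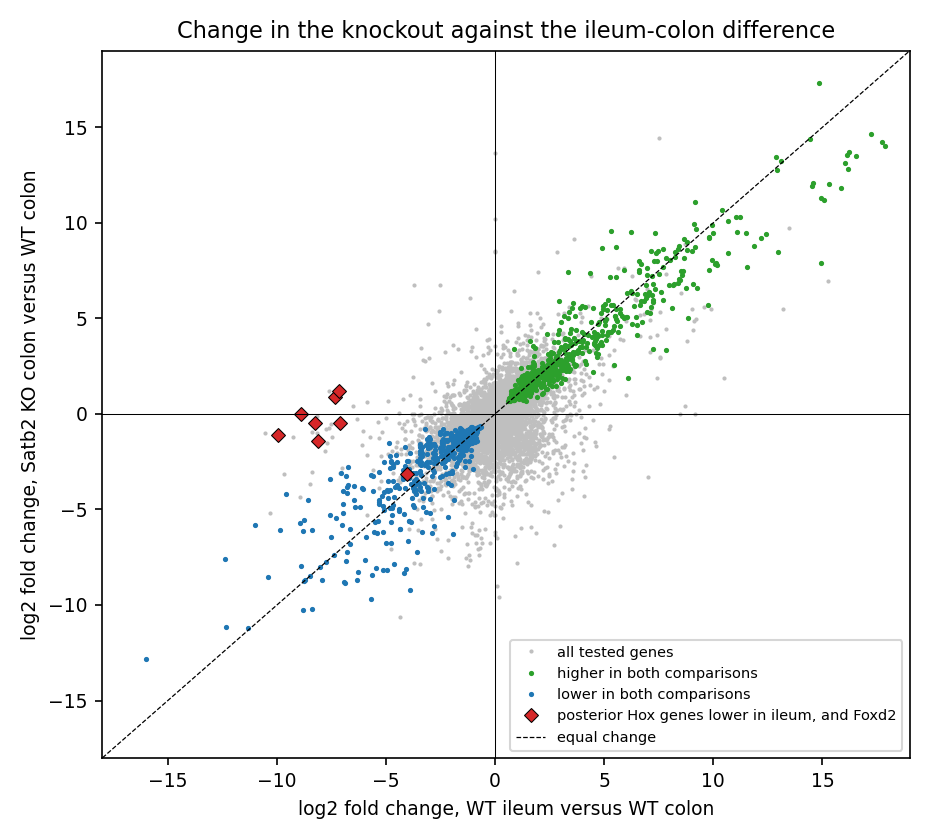
Log2 fold change of each tested gene in Satb2 KO colon against that in WT ileum, both from WT colon (n = 3 each). Green, 606 genes higher in both; blue, 437 genes lower in both; red diamonds, 7 posterior Hox genes lower in ileum, and Foxd2; the dashed line marks equal change.

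The third comparison set Satb2 KO colon beside WT ileum, and so joins tissue location with genotype. Some posterior Hox genes and Foxd2, positional genes of the colon, stayed far above the ileum level. Hoxa10 stood at 40.4 ± 28.9 CPM in Satb2 KO colon against 0.132 ± 0.0316 CPM in ileum (n = 3 each; log2 fold change 8.20 ± 0.79; edgeR, Benjamini-Hochberg-adjusted p = 0.00185). Hoxa9 stood at 22.7 ± 6.01 against 0.107 ± 0.0926 CPM (7.75 ± 0.98) and Foxd2 at 43.8 ± 17.8 against 0.433 ± 0.155 CPM (6.65 ± 0.46). Hoxa11 had 1 count in ileum, a ratio of 408 with a counting interval of 72.8 to 16134. Of 11 tested posterior Hox genes 5 were higher and 6 did not pass (9 adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 2.91e-23, and 0.00137 with an estimated correlation).

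Fewer genes separated Satb2 KO colon from ileum than from WT colon: 194 were higher and 178 lower. Without WT ileum replicate 2 the test called 68 higher and 54 lower, without WT colon replicate 2 91 and 56, without WT colon replicate 3 85 and 57, without knockout replicate 2 52 and 16, and without knockout replicate 3 70 and 41. Without WT ileum replicate 3 it called 94 higher, and without knockout replicate 1 71 lower. With the replicate number as a block it called 455 higher and 428 lower, and with library size alone 130 higher and 166 lower, a higher share of 43.9% in place of 52.2%, as the median log2 fold change of all genes moved from -0.04 to -0.18. Satb2 was higher than in ileum (103 ± 24.6 against 36.2 ± 8.36 CPM, log2 fold change 1.5 ± 0.25; edgeR, Benjamini-Hochberg-adjusted p = 0.0192). The call was lost without WT ileum replicate 2 (edgeR, Benjamini-Hochberg-adjusted p = 0.0802), knockout replicate 2 (0.0960) or knockout replicate 3 (0.0720). It was also lost with library size alone (edgeR, Benjamini-Hochberg-adjusted p = 0.0616), with the 6 libraries alone (0.0661) and by limma on RPKM (0.0599 to 0.0762).

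A few genes for the uptake of fat exceeded the ileum level. Apoa4 stood at 897 ± 113 CPM in Satb2 KO colon against 159.7 ± 17.2 CPM in ileum (log2 fold change 2.49 ± 0.23; edgeR, Benjamini-Hochberg-adjusted p = 0.00366). Fabp1 stood at 147 ± 41.6 against 15.9 ± 6.61 CPM (3.21 ± 0.41). Scarb1 was also higher than in ileum, at 21.6 ± 2.70 against 0.968 ± 0.262 CPM (4.48 ± 0.27), but stood at 20.9 ± 1.28 CPM in WT colon. Of 19 genes of fat absorption 4 were higher and 15 did not pass (7 adjusted over the list alone); their median log2 fold change was -0.02 and their mean 0.67, with the test upward (camera with Benjamini-Hochberg adjustment, p = 1.26e-05, and 0.0473 with an estimated correlation). Colonic genes that stayed above the ileum level were Retnlb (277 ± 52.7 against 3.81 ± 3.01 CPM, 6.17 ± 0.66) and St6galnac6 (61.2 ± 26.1 against 5.04 ± 2.26 CPM, 3.59 ± 0.42). The change of Retnlb from WT colon (log2 fold change -1.54) did not pass. Of 20 genes of colonic ion and water transport 6 were higher than in ileum and 14 did not pass (10 adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 3.16e-08, and adjusted p = 0.0736 with an estimated correlation). Only 3 of them were higher without any 1 of the WT colon replicates, and 2 without WT ileum replicate 3 or knockout replicate 2 or 3. Examples of the 6 were the sodium channel gene Scnn1a (132 ± 35.7 against 21.5 ± 5.43 CPM, 2.61 ± 0.36) and Hsd11b2 (114 ± 21.5 against 38.0 ± 1.19 CPM, 1.59 ± 0.22).

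Many Paneth cell genes stayed below the ileum level. Of 17 Paneth cell genes 9 were lower than in ileum and 8 did not pass (12 adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 8.76e-23, and 0.0473 with an estimated correlation). In this Paneth list 5 were lower without WT ileum replicate 3, 4 without knockout replicate 1 or 3, and 1 without knockout replicate 2. Slc25a48 (1.53 ± 1.13 against 101 ± 54.8 CPM, log2 fold change -6.01 ± 0.62), Susd2 (4.86 ± 2.19 against 109 ± 14.6 CPM, -4.49 ± 0.48) and Fam234b (4.33 ± 1.07 against 80.9 ± 30.4 CPM, -4.22 ± 0.36) were lower as well. None of the 16 brush border enzyme genes passed by edgeR over all genes, but 5 were lower adjusted over the list alone, 4 with the replicate block, 2 without WT ileum replicate 1 and 1 without knockout replicate 1 (camera with Benjamini-Hochberg adjustment, p = 0.00140, and adjusted p = 0.141 with an estimated correlation).

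**Figure D4:**
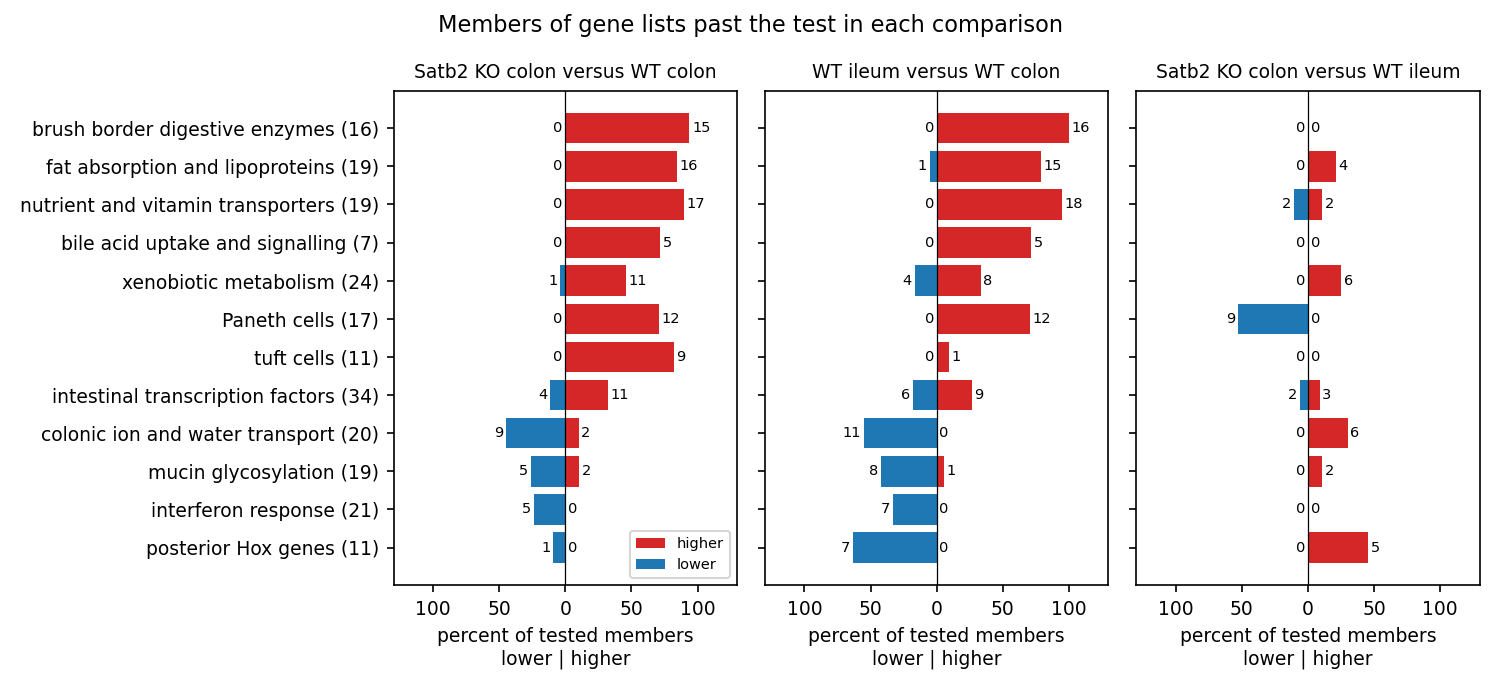
Percent of the tested members of 12 gene lists that were higher (right) or lower (left) in each of the 3 comparisons; the number of genes is printed at each bar and the number tested stands in brackets.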

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

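Tests with replicates 2 and 3 alone, with replicate 1 as a covariate, and with simulated noise also taken off the variance of the slope were chosen after the data were seen; the others were planned. The slope stayed positive, and no named gene changed direction. Median-of-ratios factors and the filter of 1 CPM left all counts of called genes within 1.5 times. Depth limits genes with few counts: fold changes against groups without a count rest on the floor of 3 counts. For each value below the cause was not tested.

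For Satb2 KO colon against WT colon, DESeq2 called 1364 higher and 1311 lower, the replicate block 1461 and 1267, replicates 2 and 3 alone 2071 and 1835, and the covariate 1721 and 1558. By limma 565 were higher on log2(RPKM + 0.1), 528 higher and 1049 lower with a pseudocount of 1, and 579 and 1103 without the filter. For WT ileum against WT colon, DESeq2 called 1349 lower, the block 1340 higher and 1399 lower, replicates 2 and 3 alone 1964 and 2126, and the covariate 1562 and 1642. For Satb2 KO colon against WT ileum, DESeq2 called 554 and 673, the block 455 and 428, replicates 2 and 3 alone 1260 and 932, the covariate 632 and 616. No filter gave 333 and 511, and the 6 libraries alone 78 and 51. There limma called 124 higher with a pseudocount of 1 and 125 without the filter. Leaving out 1 library at a time gave, in the same order of comparisons, 489 to 1152 higher and 279 to 959 lower, 546 to 1057 and 506 to 1041, and 52 to 210 and 16 to 197.

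The share of ileum-enriched genes higher in the knockout was 72.4%, 78.4% by limma, 81.7% with a pseudocount of 1, and 63.5 to 77.7% with 1 library left out. By direction only, a looser measure, it was 95.1% over all libraries. It was at least 94.8% with genes chosen on a pair of WT colon libraries and measured against the third. The share of colon-enriched genes lower in the knockout was 60.8%. It was 66.1% with library size alone, 68.2% by DESeq2, 68.7% with the block, 74.1% by limma (81.8% with a pseudocount of 1, 73.3% without the filter), 73.5% with replicates 2 and 3 alone and 71.6% with the covariate. It was 54.5% and 66.4% at thresholds of 2-fold and 8-fold, and 40.7 to 69.4% with 1 library left out. By direction only it was 94.8% over all libraries, and at least 81.1% measured against the third WT colon library. The slope of 0.637 became 0.399 without the filter, 0.671 with the filter of 1 CPM, 0.672 with the block, and 0.694 and 0.695 by limma with pseudocounts of 0.1 and 1. It was 0.668 with the covariate, 0.757 with noise also taken off the variance, and 0.551 to 0.639 with 1 library left out.

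Of the calls for 260 named gene results, 29 were lost with library size alone, 3 with median-of-ratios factors, 11 without the filter, 33 with the 6 libraries alone, 32 by limma (39 with a pseudocount of 1, 48 without its filter) and 3 with replicates 2 and 3 alone. Of the same results 99 lost the call in at least 1 fit without a library. The replicate block changed no call of a named gene. Of 111 list results, 38 lost the call of camera with an estimated correlation and 20 by fry. The block ended 3 list calls and made 3 others; library size alone ended 3 and made 2; replicates 2 and 3 alone ended 8 and made 7; the covariate ended 4 and made 3. Over all fits with 1 library left out, list calls were lost in 25 cases and gained in 29. The list of cytosolic ribosomal proteins turned from up to down without knockout replicate 1, against WT colon (limma's camera, Benjamini-Hochberg-adjusted p = 0.392 in place of 0.0192) and against WT ileum (adjusted p = 0.000123 in place of 0.197). With any 1 library left out, its limma camera p, Benjamini-Hochberg-adjusted, was 3.12e-05 to 0.392 against WT colon and 6.43e-07 to 0.805 against WT ileum. The mitochondrially encoded genes turned from up to down against WT ileum with replicates 2 and 3 alone (limma's camera, Benjamini-Hochberg-adjusted p = 0.115 in place of 0.00459).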

Other observations

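The tests of the Satb2 level, of the Hox genes, of the shared batch, of the mitochondrial share and of a proximal small intestine were chosen after the results were seen; those of lymphocyte markers and of random splits were planned.

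Some genes of Satb2 KO colon differed from both wild-type tissues, with no call between those tissues. By edgeR with Benjamini-Hochberg adjustment 43 such genes were higher and 34 lower than in both. The missing call is not a sign of equal levels, since edgeR recovered only 51% of simulated 4-fold changes between WT ileum and WT colon. That share was for genes with a mean of at least 20 counts, and genes with fewer counts were not covered. The lower genes were not sorted by cell type, and the count does not separate the epithelium from other cells. As an example Cytip, known from leukocytes, stood at 0.791 ± 0.591 CPM in Satb2 KO colon against 9.83 ± 2.25 CPM in WT colon and 16.2 ± 5.13 CPM in WT ileum (log2 fold changes -3.59 ± 0.52 and -4.31 ± 0.53). The genes named here were chosen after their values were seen, for passing in every fit with 1 library left out. Por, which encodes the electron donor of cytochrome P450 enzymes, stood at 558 ± 135 CPM in Satb2 KO colon (n = 3 each), 174 ± 22.3 CPM in WT colon and 113 ± 3.60 CPM in WT ileum (log2 fold changes 1.68 ± 0.24 and 2.31 ± 0.24). The lipid droplet gene Cidec stood at 69.9 ± 6.29 against 8.59 ± 2.74 and 13.9 ± 1.70 CPM (3.02 ± 0.27 and 2.33 ± 0.26), and Renbp at 52.7 ± 18.2 against 0.598 ± 0.259 and 1.08 ± 0.356 CPM (6.44 ± 0.46 and 5.59 ± 0.44). Zfp503 was lower, at 0.875 ± 0.107 against 13.0 ± 2.28 and 13.5 ± 3.34 CPM (-3.88 ± 0.31 and -3.94 ± 0.32). The count of such genes was 16 higher and 14 lower without WT ileum replicate 2, 20 and 11 without WT colon replicate 2, and 20 and 10 without WT colon replicate 3. It was 12 and 4 without knockout replicate 2, and 14 and 5 without knockout replicate 3. Further, 19 were higher without WT ileum replicate 3 and 18 lower without knockout replicate 1.

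A pair of T cell genes stood lower in Satb2 KO colon than in WT ileum. Of 12 tested genes 2 were lower and 10 did not pass (10 adjusted over the list alone; camera with Benjamini-Hochberg adjustment, p = 2.85e-07, and adjusted p = 0.296 with an estimated correlation). Cd8a stood at 2.34 ± 0.381 against 24.5 ± 24.5 CPM (log2 fold change -3.39 ± 0.73; edgeR, Benjamini-Hochberg-adjusted p = 0.0470) and Cd3e at 0.716 ± 0.266 against 9.70 ± 9.62 CPM (-3.73 ± 0.78). In these libraries the calls of both genes depended on the whole set: 6 T cell genes were lower without WT ileum replicate 3, and neither gene passed when any other library was left out. The T cell markers of WT ileum replicate 1 were 2.87 higher on the log2 scale than those of its replicates 2 and 3. Other lists were called downward too: B and plasma cells (camera with Benjamini-Hochberg adjustment, p = 1.91e-06, and adjusted p = 0.249 with an estimated correlation), myeloid cells (0.00016, and 0.248) and MHC class II (7.05e-06, and 0.274). No gene of these 3 lists passed by edgeR over all genes, while 7 of 8, 2 of 10 and 4 of 7 were lower adjusted over the list alone. With the replicate block 5 genes of B and plasma cells and 6 of MHC class II passed; 4 of the former passed without WT ileum replicate 1, and 1 of the latter without WT colon replicate 1 or knockout replicate 1.

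Satb2 kept 48.4% of its WT colon level in the knockout. If cells that escaped recombination carried these reads, colon-enriched genes would keep at least a like share, yet 40.8% of them (180 of 441) fell below the share of Satb2 by more than 2 times the standard errors. This speaks against escaped cells as the only source, and Car1 at 2.70 CPM is an example. Transcripts that lack only the deleted part may also be counted; the kept 48.4% covers the whole gene, and values per exon, which would tell, were not available.

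Posterior Hox genes and Foxd2 stood, by their median, nearer the WT colon level in the knockout than other genes that were far lower in ileum than in colon. The 7 Hox genes and Foxd2 had a median log2 fold change of -0.49 from WT colon (quartiles -1.18 and 0.21). The 71 other genes had -4.19 (quartiles -6.16 and -2.66), a difference of 3.70 on the log2 scale. Only the 71 were held to a mean log2 CPM of at least 3. Some of them were still expressed in ileum, such as Cyp2c55 at 86.1 CPM and Fut2 at 17.5 CPM. Ileum tissue in the knockout libraries, by mixing or a wrong label, would dilute both sets alike. The test speaks against ileum tissue as the only cause of the lower levels. It cannot exclude that a part of the tissue was ileum. The genes varied: of the WT colon level Hoxd8 kept 11.1%, Hoxa7 36.96%, Hoxb13 47.0% and Hoxa11 227%. With replicates 2 and 3 alone 5 of 11 Hox genes passed as lower than in WT colon and 1 as higher.

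Replicate 1 of each group stood apart: the spread within groups, as chi-square per degree of freedom, was 201 to 389 for pairs with replicate 1, and 23.1, 31.3 and 50.6 for replicates 2 and 3 of WT colon, Satb2 KO colon and WT ileum. The deviations of the 3 replicate 1 libraries from their group means correlated at 0.422 or more, as a batch shared by them would produce. The second principal component had already placed these libraries on the same side, so the correlation is not separate evidence. The mitochondrial share of replicates 1 to 3 was 15.4, 4.64 and 4.57% in Satb2 KO colon, 1.98, 5.58 and 5.6% in WT colon, and 2.27, 5.78 and 6.30% in WT ileum. Replicate 1 differed from the others by 1.74 in Satb2 KO colon, -1.50 in WT colon and -1.41 in WT ileum on the log2 scale. This speaks against damage that moves these transcripts 1 way. The share of ribosomal protein transcripts did move 1 way. In replicates 1 to 3 it was 6.22, 1.74 and 1.73% in Satb2 KO colon and 3.67, 1.69 and 1.79% in WT colon. In WT ileum it was 5.30, 1.55 and 2.01%. Knockout replicate 1 also had the fewest genes with counts of the 9 libraries (16868). Another difference in RNA or library quality therefore stays open. The summed level of the goblet cell genes was also lower in replicate 1 of each group. In replicates 1 to 3 it was 13657, 20005 and 28120 CPM in WT ileum. In WT colon it was 10612, 46446 and 36861 CPM, and in Satb2 KO colon 7224, 35195 and 39419 CPM. A different share of goblet cells was not tested. T cell markers of replicate 1 were higher by 2.87 in WT ileum, 0.98 in WT colon and 0.065 in Satb2 KO colon, where replicates 2 and 3 differed by 0.0999, so a difference in lymphocytes stays open. The batch, if there was one, was shared by the 3 groups, and the fit with replicate 1 as a covariate called 1721 higher and 1558 lower genes in the knockout against WT colon.

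A few fat absorption genes above the ileum level raised the hypothesis that the knockout colon resembles a more proximal part of the small intestine. A list of 16 duodenal and jejunal genes (14 tested, 6 of them in other lists) did not differ between Satb2 KO colon and WT ileum (median log2 fold change -0.05; camera with an estimated correlation, unadjusted p = 0.694), so the test leaves the hypothesis open. Of the 14 tested genes 7 were higher in WT ileum than in WT colon (camera with an estimated correlation, unadjusted p = 0.0113). No duodenum or jejunum was measured, so the list was not shown to separate these parts from ileum. Among the genes of this list Slc40a1 stood at 158 against 20.6 CPM and Ada at 135 against 158 CPM, and neither passed.

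Of the 10 splits of 6 libraries into 3 and 3, including the real one, 1 gave as large a result as the groups in each test, the real split itself. It had 1575 genes called for Satb2 KO colon against WT colon, 1740 for WT ileum against WT colon, 372 for Satb2 KO colon against WT ileum, and shares of 72.4% and 60.8%. The highest count in another split was 3 for WT ileum against WT colon and 1 for Satb2 KO colon against WT ileum, and no gene was called in another split of Satb2 KO colon and WT colon by edgeR with Benjamini-Hochberg adjustment. With 10 splits, a share under 0.05 is out of reach. Every other split also put libraries of both groups on each side. A difference between the groups then adds to the spread, so these splits could hardly call a gene and do not measure chance.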
